A study of Mus musculus with 15 samples.

How the data were processed

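RNA from B16-F10 cells, a mouse melanoma line, was sequenced in 15 libraries, 3 in each of 5 groups. Per the labels, cells were given DMSO (the vehicle), 2 µM GSK126 or 2 µM DZNep in a compound arm, and a scrambled siRNA (scr) or an siRNA against Ezh2 (siEzh2) in a parallel siRNA arm. GSK126 is an inhibitor of the methyltransferase activity of EZH2, and DZNep (3-deazaneplanocin A) inhibits S-adenosylhomocysteine hydrolase. Total RNA was taken up on a column with a DNA removal step, per the labels. The duration of each treatment, the siRNA sequences and the library kit are not given in the sources used here.

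The values used were the whole-number read counts per gene that the authors deposited, with no normalization. Reads were aligned with STAR to GRCm38 and counted with featureCounts, per the submitters' processing notes. The versions, the gene annotation and the strand setting are not given in the sources used here. Reads of genes that overlap, of antisense transcripts and of near-identical family members could therefore be split or shared. Some such genes are named as uncertain, but not every named gene with an overlap is marked. The table held 46078 gene identifiers. Of these, 45143 matched GENCODE M21, an annotation of GRCm38, which gave symbols and coordinates, and the other 935 held 0.0588% of the counts.

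Each column was assigned to its library by its name in the labels. The numbers at the end of the library names place GSK126 replicate 1 near the siRNA arm and apart from the other compound libraries, so the results for GSK126 were also computed without it. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom between 5.96 and 38.8 over the pairs, so every library was counted. Nothing says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

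Total counts per library lay between 33299524 and 64545747, and 1 count was worth between 0.0155 and 0.03 CPM. Levels are given as CPM on TMM-scaled library sizes, as mean ± SD of 3 libraries. A group with 3 counts or fewer over its libraries was taken as at the floor, and such floors cover counting error only.

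Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and robust estimation, in 1 fit of all 15 libraries with a term per group and no covariate. The low-count filter of edgeR left 15152 genes. The common dispersion was 0.00409, a coefficient of variation of 6.4% between libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are log2 values ± standard error, and every adjusted p of a gene comes from this edgeR fit unless another setting is named beside it. The comparisons were GSK126 with DMSO, DZNep with DMSO, siEzh2 with scr, the siEzh2 effect minus the GSK126 effect, the DZNep effect minus the siEzh2 effect (each effect against its own control), DZNep with GSK126, and scr with DMSO.

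There were 24 fixed gene lists with 707 listed symbols. They covered PRC2 subunits, pigmentation and melanocyte lineage, the vacuolar ATPase, clathrin coat and adaptors, lysosome, ribosome biogenesis, cytosolic ribosomal proteins, S phase, G2 and M phase, p53 targets, interferon-stimulated genes, MHC class I presentation, developmental regulators bound by PRC2, cholesterol synthesis, the integrated stress response (ATF4 targets), the endoplasmic reticulum unfolded protein response, the methionine cycle and polyamines, mesenchymal and invasion genes, imprinted genes, germline genes, neural and neuronal genes, markers of fibroblasts, markers of blood and endothelial cells, and mitochondrially encoded genes as a sign of RNA quality. Each was tested against the other genes with camera of limma 3.58.1 at an inter-gene correlation of 0.01, and adjusted over 72 tests (24 lists in 3 main comparisons), or over 24 lists in each other comparison. The test was repeated with an estimated correlation, and fry was run as a test of movement in 1 direction. An adjusted p of a list is from camera with the set correlation unless stated. In GSK126 with DMSO, only pigmentation kept its call with an estimated correlation. In DZNep with DMSO, the p53 target, ATF4 target and fibroblast lists kept theirs, and in siEzh2 with scr the pigmentation, interferon and PRC2 lists did.

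Genes named in the text followed a rule. Ezh2 and Ezh1 were given throughout. For each main comparison the rule took the 6 largest increases and the 6 largest decreases among called genes whose 3 treated libraries lay beyond all 3 controls, with a mean of at least 2 CPM and no predicted or clone symbol. It added the 3 pigmentation genes with the smallest p and, from the 7 other lists with the smallest camera p, the 2 members with the smallest p and, where members were called both ways, the first in the other direction. For the remaining comparisons it took the 3 largest changes each way. Other members are named only to show who moved in a list and were chosen after their values were seen. Results of a few genes were left out because their names are withheld for evaluation, so some members of small counts are not named. The grouping, tests, lists, naming rule and main alternatives were set before the data were examined.

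The alternatives were RLE size factors, no count filter, DESeq2 1.42.0, only the compared groups in the fit, the replicate number within each arm as a block, each library left out in turn, an absolute log2 fold change of at least 1, and the estimated correlation. DMSO as the control of siEzh2, scaling by library totals alone, and the PRC2 list without Ezh2 were added after seeing the data. In a difference between effects DMSO then cancels. That leaves siEzh2 directly against GSK126, or DZNep directly against siEzh2, across the arms, where transfection and handling are confounded. Words of 7 bases in annotated 3′ UTRs were compared by a t-test of fold changes after removing trends with UTR length and GC content. Correlations and overlaps between comparisons were set beside 20 simulations of unchanged groups with the same controls. Every scaling used centres the libraries, so a shift of all genes together was not tested.

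The edgeR steps were tested on simulated data with known changes, drawn from the libraries' own means. For GSK126 with DMSO, 44% of genes changed by 1.25-fold, 73.5% at 1.5-fold, 88% at 2-fold and 94% at 4-fold were recovered among 14937 genes, and 4.49% of calls were false. For DZNep with DMSO these shares were 46%, 69.4%, 84% and 100% among 14932 genes, with 8.59% false. For siEzh2 with scr they were 44%, 64%, 82% and 98% among 14930 genes, with 3.36% false.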

Results

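Gene expression was measured by RNA sequencing in B16-F10 mouse melanoma cells, a pigmented tumour line, after treatments that act on EZH2, the catalytic subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3 at lysine 27. Cells were given DMSO, 2 µM GSK126 or 2 µM DZNep, and in parallel a scrambled siRNA (scr) or an siRNA against Ezh2 (siEzh2), with 3 libraries per group. Total counts per library were 42087020, 43721698 and 64545747 in DMSO, 36855662, 43465903 and 41741072 with GSK126, and 34690674, 42695833 and 43712190 with DZNep. They were 49221045, 47448283 and 38599777 in scr and 33299524, 39436682 and 43261642 with siEzh2. Mitochondrially encoded transcripts, a sign of RNA quality, took 8.69% ± 0.501 of counts in DMSO, 9.68% ± 0.887 with GSK126, 7.39% ± 1.13 with DZNep, 9.17% ± 1.87 in scr and 8.34% ± 0.851 with siEzh2 (SD, n = 3 each). The first principal component held 60.1% of the variance and set the DZNep libraries apart from the other 4 groups, and the second held 10.2%.

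**Figure D1:**
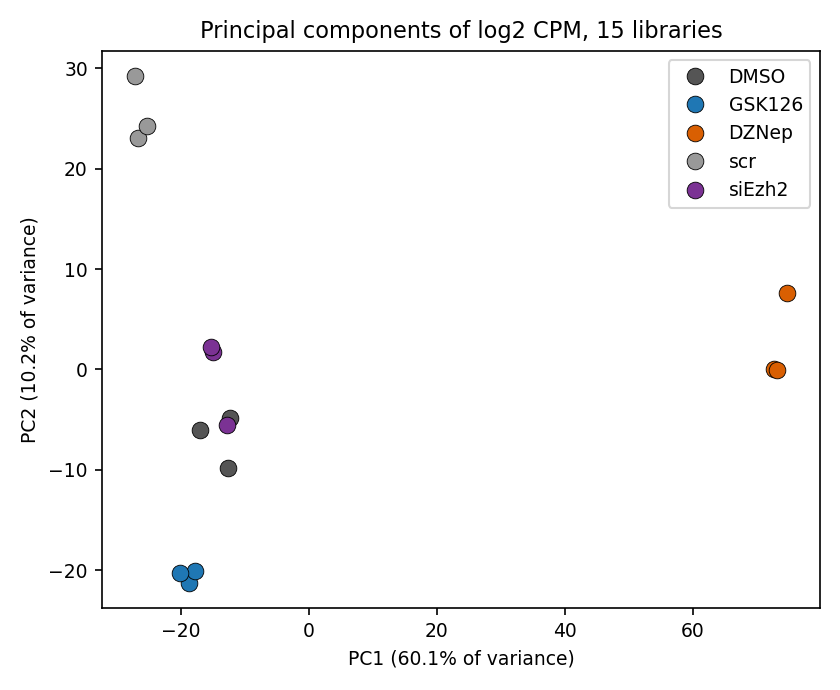
Each point is a library on the first 2 principal components of log2 CPM, coloured by group, with the share of variance on each axis. The 3 DZNep libraries lie apart on the first component (60.1% of the variance).

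Ezh2 itself (ENSMUSG00000029687, chromosome 6, 47530139 to 47595341, GRCm38, minus strand) stood at 219 ± 6.59 CPM in scr and 39.6 ± 1.87 CPM with siEzh2 (SD, n = 3). That was a 5.53-fold lower level in the knockdown (log2 fold change −2.47 ± 0.05, adjusted p = 1.22e-17), and all siEzh2 libraries matched their label. DZNep lowered Ezh2 transcripts 1.33-fold, from 207 ± 2.66 to 155 ± 5.06 CPM (−0.41 ± 0.05, adjusted p = 3.67e-07), whereas with GSK126 the level was 214 ± 6.81 CPM (0.05, adjusted p = 0.569). In scr it differed from DMSO by 0.08 (adjusted p = 0.221), and siEzh2 lay at −2.39 against DMSO. The Ezh2 difference between effects was −2.52 for siEzh2 minus GSK126 (adjusted p = 2.98e-15) and 2.06 for DZNep minus siEzh2 (adjusted p = 2.67e-14), and DZNep lay at −0.46 against GSK126 (adjusted p = 6.97e-08). The predicted gene Gm26625 overlaps Ezh2 on the other strand, so the share of its reads is uncertain.

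Ezh1, the paralogous methyltransferase subunit (ENSMUSG00000006920, chromosome 11, 101191115 to 101226463), had a log2 fold change of −0.16 with GSK126 (adjusted p = 0.163), 0.17 with DZNep (adjusted p = 0.0421), 0.02 with siEzh2 (adjusted p = 0.873) and 0.07 in scr against DMSO (adjusted p = 0.506). DZNep against GSK126 gave 0.33 (adjusted p = 0.000495). The differences between effects were 0.18 for siEzh2 minus GSK126 (adjusted p = 0.244) and 0.15 for DZNep minus siEzh2 (adjusted p = 0.221). With DMSO as the control of siEzh2, which compares siEzh2 directly with GSK126, the first was 0.25 (adjusted p = 0.019). The Ezh1 call with DZNep was lost without DMSO replicate 1 (adjusted p = 0.0783), DMSO replicate 2 (0.148) or DZNep replicate 3 (0.231), with library totals alone (0.0874) and with only the compared groups in the fit (0.066).

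**Figure D2:**
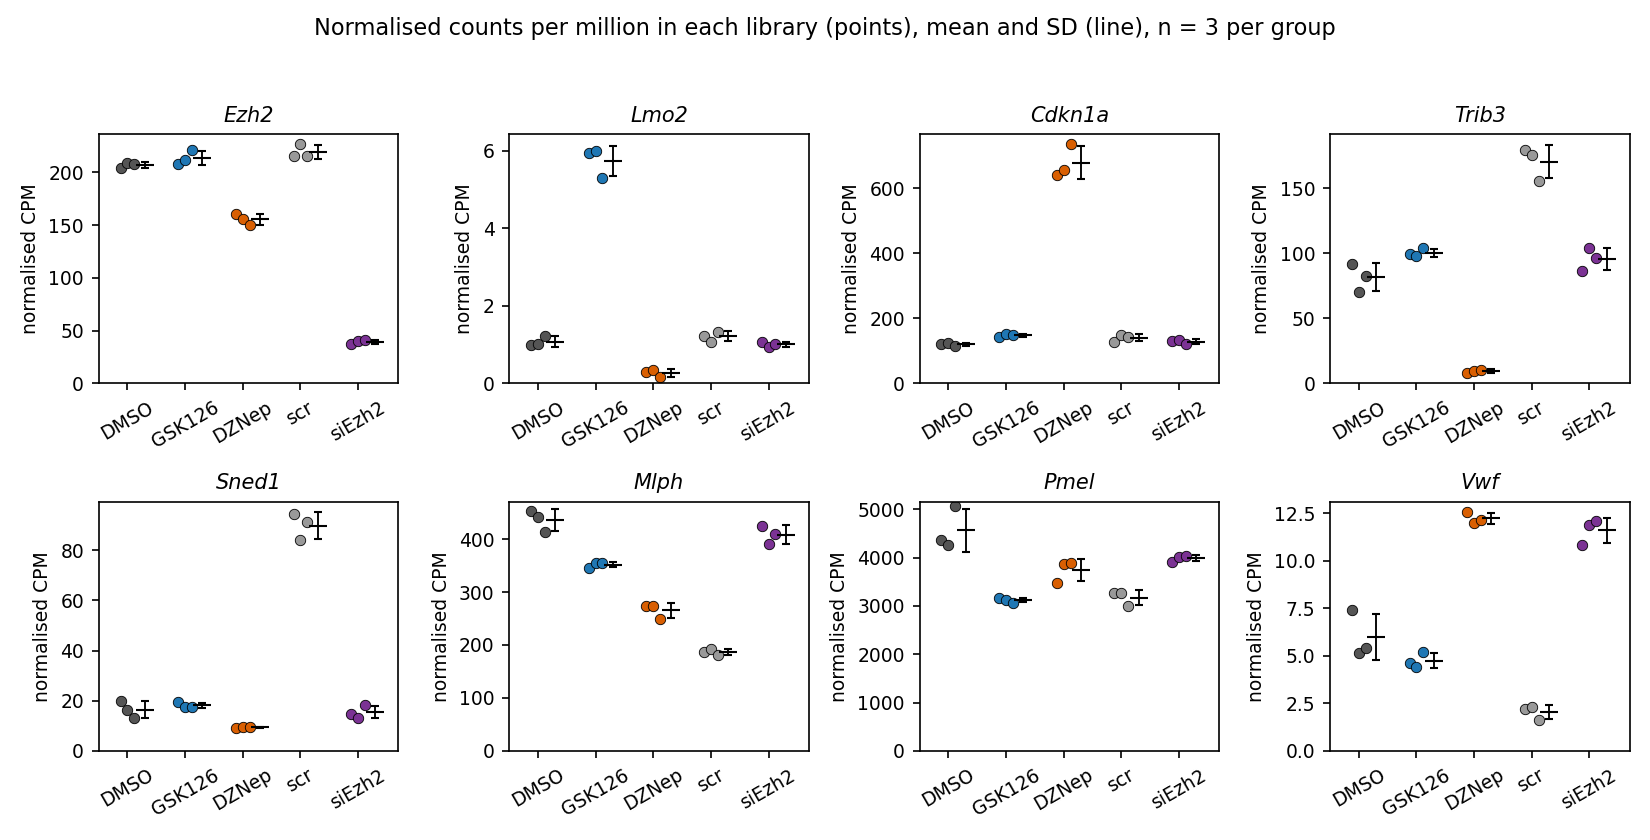
CPM of 8 genes in every library on a linear axis, with the mean and SD of the 3 libraries per group. Ezh2 falls to 39.6 CPM with siEzh2, Lmo2 rises with GSK126, Cdkn1a rises and Trib3 falls with DZNep, and Sned1, Mlph and Vwf differ between the DMSO and scr controls.

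Among the genes that the naming rule admits, the largest increases with GSK126 were in Sema3c, Lmo2 and Pcdh17. Sema3c, a secreted semaphorin (chromosome 5, 17574281 to 17730268), rose from 6.02 ± 0.498 to 33.1 ± 2.09 CPM, 5.51-fold (log2 2.46 ± 0.10, adjusted p = 8e-13, SD of n = 3). Lmo2, a LIM-domain transcription cofactor of blood cell development (chromosome 2, 103957986 to 103981878), rose 5.25-fold from 1.08 ± 0.134 to 5.75 ± 0.388 CPM (2.39 ± 0.14). Pcdh17, a protocadherin (chromosome 14, 84443563 to 84539002), rose 4.57-fold (2.19 ± 0.08), and the cell adhesion molecule Cntn1 rose 2.9-fold from 31.9 ± 2.5 to 92.5 ± 2.1 CPM. Itgb8, an integrin beta chain, and Nckap5 rose 3.01-fold and 2.95-fold. The largest decreases among the admitted genes were those of Sgk2, a serine/threonine kinase (3.48-fold lower, −1.80 ± 0.13, adjusted p = 5.29e-09), Dhrs3, a retinaldehyde reductase (2.08-fold lower), Nwd1 (−0.85 ± 0.14) and Mmp15, a membrane-bound matrix metalloproteinase (−0.82 ± 0.09). Rapgef3os1 and Rapgef3os2 also fell (−0.96 ± 0.11 and −0.86 ± 0.08), but both lie antisense to Rapgef3 and their reads could not be told from those of that gene.

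Pigment cell genes fell with GSK126. Of 33 measured pigmentation and melanocyte genes, 18 fell, or 21 when adjusted over the list alone (mean log2 −0.215, adjusted p = 4.4e-12, and adjusted p = 0.000966 with an estimated correlation). Pmel, the fibril protein of the melanosome (chromosome 10, 128704195 to 128720238), fell 1.46-fold from 4560 ± 435 to 3120 ± 46.6 CPM (−0.55 ± 0.06, adjusted p = 5.91e-06), Tspan10 changed by −0.52 ± 0.06 and Hps4, which acts in melanosome biogenesis, by −0.53 ± 0.07. Pmel overlaps Cdk2 and Dgka on the other strand. The vacuolar ATPase acidifies organelles, and 10 of its 16 genes fell, or 13 when adjusted over the list alone (adjusted p = 1.03e-07, and adjusted p = 0.144 with an estimated correlation). Atp6v1g1 stood at −0.36 ± 0.06 and Atp6v1b2 at −0.29 ± 0.06. Of 30 lysosome genes, 10 fell, or 13 when adjusted over the list alone (adjusted p = 3.68e-06, and adjusted p = 0.147 with an estimated correlation). Among them were the protease Ctsb (−0.37 ± 0.06) and the thioesterase Ppt1 (−0.28 ± 0.05). Of 21 endoplasmic reticulum unfolded protein response genes, 7 fell, or 8 when adjusted over the list alone (adjusted p = 0.000823, and adjusted p = 0.358 with an estimated correlation). The ubiquitin ligase Syvn1 (−0.33 ± 0.07) and Creld2 (−0.28 ± 0.07) had the smallest p among them. The Creld2 call was lost without DMSO replicate 3 (adjusted p = 0.0773) or GSK126 replicate 3 (0.0697) and with only the compared groups in the fit (0.0582).

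Among 35 interferon-stimulated genes, 6 fell and 1 rose with GSK126, or 12 and 1 when adjusted over the list alone (mean log2 −0.195, adjusted p = 0.00138, and adjusted p = 0.229 with an estimated correlation). Ifit1, an RNA-binding antiviral effector, fell by 0.45 ± 0.08 while Cmpk2, a mitochondrial nucleotide kinase, rose by 0.66 ± 0.07 on the log2 scale. Imprinted genes had 3 of 10 members higher, or 3 higher and 1 lower when adjusted over the list alone, with a median of −0.01 against a mean of 0.157 and a test for higher values (adjusted p = 0.00804, and adjusted p = 0.144 with an estimated correlation; 0.121 with no count filter). These were Mest (2.73-fold, 1.45 ± 0.09; its locus overlaps Copg2), Peg10 (0.72 ± 0.09) and Sgce, the last named after its values were seen. Mesenchymal and invasion genes had 8 of 30 higher and 1 lower (Mmp2, named after its values were seen), or 9 and 3 when adjusted over the list alone (adjusted p = 0.0102, and adjusted p = 0.147 with an estimated correlation). Integrated stress response genes, targets of ATF4, had 7 of 28 higher, or 9 higher and 1 lower when adjusted over the list alone (adjusted p = 0.0102, and adjusted p = 0.584 with an estimated correlation). The stress-induced cofactor Nupr1 stood at 0.43 ± 0.07 and the lipoprotein receptor Vldlr at 0.39 ± 0.08. That list was not called without DMSO replicate 2 (adjusted p = 0.134) and its adjusted p was 0.0534 by fry. Neural genes had 4 of 10 higher and 2 lower by either adjustment, over all genes or adjusted over the list alone (adjusted p = 0.0232, and adjusted p = 0.144 with an estimated correlation). The neural call was lost without DMSO replicate 1 (adjusted p = 0.0629), with the compared groups only (0.0523) and with no count filter, where the mean turned to −0.016 (0.0921). Cytosolic ribosomal proteins had 3 of 40 lower, also when adjusted over the list alone (adjusted p = 0.00878, and adjusted p = 0.631 with an estimated correlation; 0.132 by fry). Rps4x stood at −0.23 ± 0.05 and Rps15 at −0.25 ± 0.07, and the third was Rps3, named after its values were seen. Without DMSO replicate 3 the mean of the ribosomal list was −0.033 (adjusted p = 0.303), and Rps15 was not called without DMSO replicate 3 (0.156), GSK126 replicate 1 (0.13) or GSK126 replicate 3 (0.0648), by library totals (0.052) or in the compared groups only (0.0828).

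The other lists were not called with GSK126. Of 13 PRC2 subunits, Rbbp4, Aebp2 and Rbbp7 fell, 3 in all, or 5 when adjusted over the list alone (adjusted p = 0.11; 0.0233 with no count filter). Of 36 developmental regulators bound by PRC2 that passed the count filter (82 were listed), 4 rose and 1 fell, or 4 and 2 when adjusted over the list alone (mean 0.07, adjusted p = 0.313). Those were the transcription factors Foxa1, Hoxd13, Tbx15 and Hoxa10, and the lower Irx3. p53 targets had 5 of 27 higher (Perp, Polk, Plk2, Tnfrsf10b and Cdkn1a), or 5 higher and 1 lower when adjusted over the list alone (adjusted p = 0.173). Clathrin coat genes had Eps15, Hip1 and Picalm higher, 3 of 20, or 3 higher and 2 lower when adjusted over the list alone, with a median of −0.095 (adjusted p = 0.398). Of 51 G2 and M phase genes Cdc20 fell, the same when adjusted over the list alone (adjusted p = 0.468), and of 40 ribosome biogenesis genes Nop10 fell, which did not pass when adjusted over the list alone (adjusted p = 0.681). Fibroblast markers had Col1a2 higher and Col1a1 and Fbln1 lower of 6, or 2 and 2 when adjusted over the list alone, with a median of −0.035, a mean of −0.01 and a test leaning to higher values (adjusted p = 0.776). Of 2 measured blood and endothelial markers Fcer1g fell, also when adjusted over the list alone (adjusted p = 0.382). In MHC class I presentation Nlrc5 rose and Tapbp fell of 16, the same when adjusted over the list alone (adjusted p = 0.977). Methionine cycle and polyamine genes had 2 of 20 higher (Adk and Ahcyl1) and 3 lower (Mat2b, Adi1 and Enoph1), or 4 and 5 when adjusted over the list alone, with a median of 0.071 and a mean of −0.003 (adjusted p = 0.977). Cholesterol synthesis had 2 of 25 higher, Hsd17b7 and Stard4, neither of which passed when adjusted over the list alone, with a median of 0.001 and a mean of −0.007 (adjusted p = 0.977). By edgeR, 0 of 41 S phase, 0 of 13 mitochondrially encoded and 0 of 4 germline genes were called, over all genes or adjusted over the list alone (adjusted p = 0.659, 0.492 and 0.313). At an unadjusted p under 0.05 these lists held 5, 0 and 2 members, and DESeq2 called 1 S phase gene and 0 in the other lists. Members named in these uncalled lists were chosen after their values were seen.

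In all, GSK126 changed 1923 of 15152 genes (12.7%), 1084 upward and 839 downward, of which 133 rose and 19 fell at least 2-fold. The share of calls that were higher was 56.4%, or 64.4% with library totals alone. The count fell to 1251 without GSK126 replicate 1, 1201 without replicate 2, 1216 without replicate 3 and 1249 without DMSO replicate 3, and to 1131 with only the compared groups in the fit.

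DZNep was given at the same 2 µM. Prl2c5, of the prolactin family (chromosome 13, 13182715 to 13191923), rose 128-fold, from 0.0598 ± 0.0111 to 8.07 ± 0.385 CPM (SE 0.29 on the log2 scale, adjusted p = 6.63e-14), though the family's members are alike and its reads are uncertain. Cyp4a10, a fatty acid hydroxylase with close paralogs, rose 93.7-fold to 4.05 ± 0.287 CPM, from 6 counts over the 3 DMSO libraries. The collagen Col14a1 rose 33.8-fold from 1.18 ± 0.102 to 39.5 ± 0.624 CPM (5.08 ± 0.12), the muscle genes Neb (nebulin) and Atp2a1 (a sarcoplasmic calcium pump) rose 34.7-fold and 29.7-fold, and Duox1, an oxidase that forms hydrogen peroxide, rose 21.5-fold. Akr1b7, an aldo-keto reductase (chromosome 6, 34412334 to 34423142), fell 251-fold from 13.3 ± 2.21 to 0.0492 ± 0.0401 CPM (−7.97 ± 0.31, adjusted p = 1.17e-12). Lower as well were Apobr, a lipoprotein receptor (34.5-fold), G0s2, an inhibitor of triglyceride lipase (15.2-fold), the metalloproteinase Mmp11 (log2 −3.81 ± 0.18), Odf3l1 (11.6-fold) and the collagen Col20a1 (11.6-fold). Neb, Atp2a1, Akr1b7 and Apobr overlap other annotated genes, which leaves part of their reads uncertain.

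Targets of p53 rose and targets of ATF4 fell with DZNep. Of 27 p53 targets, 22 rose and 3 fell, or 23 and 3 when adjusted over the list alone (mean 1.298, adjusted p = 1.91e-22, and adjusted p = 0.000751 with an estimated correlation). Cdkn1a, the cyclin-dependent kinase inhibitor p21 (chromosome 17, 29090976 to 29100727), rose 5.65-fold from 120 ± 4.37 to 678 ± 50.5 CPM (2.50 ± 0.07, adjusted p = 1.1e-16), and the kinase Plk2 rose 6.77-fold. Rrm2b, a ribonucleotide reductase subunit, fell (−0.86 ± 0.09), as did Sesn2 and Epha2, both named after their values were seen. Of 28 integrated stress response genes 24 fell and 1 rose, the same numbers when adjusted over the list alone (mean −1.101, adjusted p = 2.47e-21, and adjusted p = 0.0448 with an estimated correlation). Vldlr fell 6.54-fold, Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, fell 2.86-fold, and the amino acid transporter Slc7a3 rose 3.79-fold. Cdkn1a overlaps a clone-named gene on the other strand.

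Cell cycle, fibroblast marker and ribosome lists were also called with DZNep. Of 51 G2 and M phase genes 39 rose with DZNep, also when adjusted over the list alone (adjusted p = 1.25e-09, and adjusted p = 0.218 with an estimated correlation). The mitotic microtubule proteins Gtse1 and Psrc1 rose 3.42-fold and 3.44-fold. S phase genes had 25 of 41 higher and 5 lower, or 26 and 6 when adjusted over the list alone (adjusted p = 0.0025, and adjusted p = 0.509 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, stood at 0.74 ± 0.05 and the replication licensing factor Cdc6 at 0.68 ± 0.05, against −0.46 ± 0.08 for Dscc1. The other 4 lower genes, named after their values were seen, were Ubr7, Hells, Rfc2 and Pola1. Fibroblast markers had 4 of 6 higher, also when adjusted over the list alone (adjusted p = 0.000337, and adjusted p = 0.0261 with an estimated correlation). They were Postn (periostin, 6.9-fold), Fbln1 (0.89 ± 0.07), Col1a1 and Col1a2, the last pair named after their values were seen. Ribosome biogenesis had 23 of 40 higher and 5 lower by both adjustments, over all genes and adjusted over the list alone (adjusted p = 0.00624, and adjusted p = 0.447 with an estimated correlation). The nucleolar proteins changed by 0.77 ± 0.05 (Nop2), 0.80 ± 0.07 (Nop16) and −0.50 ± 0.05 (Npm1). Cytosolic ribosomal proteins had 23 of 40 lower and 1 higher, also when adjusted over the list alone (mean −0.299, adjusted p = 0.0232, and adjusted p = 0.692 with an estimated correlation). Rpl4 changed by −0.69 ± 0.07 and Rpl5 by 0.28 ± 0.09. Without DMSO replicate 3 the ribosomal list was at −0.194 (adjusted p = 0.0973). The call of Rpl5 was lost without DMSO replicate 1 (adjusted p = 0.0785) or 2 (0.0519) and without DZNep replicate 1 (0.0697) or 3 (0.0597), and ribosomal protein genes have many processed copies whose reads cannot be told apart.

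Pigmentation genes split with DZNep, 15 of 33 higher and 10 lower, the same when adjusted over the list alone (mean 0.177, adjusted p = 0.056). The list passed without DZNep replicate 1 (adjusted p = 0.0475) or replicate 3 (0.0438) and with the replicate number as a block (0.0487). Kit, the receptor for stem cell factor (chromosome 5, 75574916 to 75656722), rose 4.26-fold from 33.3 ± 1.28 to 142 ± 3.35 CPM, Rab32, a GTPase of melanosome traffic, rose 2.99-fold and the neural crest transcription factor Tfap2a rose 2.45-fold. The other lists were not called as groups, and their numbers of higher and lower members over all genes were the same when adjusted over the list alone, except where both are given. Cholesterol synthesis had 3 (Tm7sf2, Dhcr7 and Ebp) and 15 of 25, or 4 and 15 when adjusted over the list alone (adjusted p = 0.0858), and passed with no count filter (0.00396) and without DMSO replicate 1 (0.0467). The unfolded protein response had 10 and 4 (Sel1l, Dnajc3, Edem1 and Herpud1) of 21 (adjusted p = 0.0918), interferon-stimulated genes 16 and 7 of 35, or 16 and 8 when adjusted over the list alone (0.11), and the methionine cycle and polyamines 10 and 2 of 20 (0.161, and 0.0438 with no count filter). MHC class I presentation had 7 higher and H2-Q4 lower of 16 (adjusted p = 0.364), germline genes had Tdrd9 and Tuba3b higher and Ddx4 lower of 4 (0.487), and of 2 blood and endothelial markers Fcer1g was higher (0.673). Mesenchymal genes had 13 and 12 of 30 (adjusted p = 0.63), and developmental regulators bound by PRC2 had 11 and 14 of 36 (0.63). Neural genes had 3 and 3 of 10 with a median of −0.07 and a mean of 0.03 (adjusted p = 0.63), lysosome genes 9 and 11 of 30 with 0.001 and −0.032 (0.669), and the vacuolar ATPase 4 and 5 of 16 with 0.03 and −0.039 (0.767). Mitochondrially encoded genes had 1 (mt-Co3) and 1 (mt-Nd1) of 13 (adjusted p = 0.831), clathrin genes 8 and 6 of 20 (0.988), and PRC2 subunits 5 and 5 of 13 with a median of 0.092 and a mean of −0.023 (0.929). Imprinted genes had Peg10 and Mest higher and Plagl1, Sgce, Cdkn1c and Phlda2 lower of 10, with a median of −0.141, a mean of −0.178 and a test leaning to higher values (adjusted p = 0.937). Members named in these uncalled lists were chosen after their values were seen.

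Across the transcriptome DZNep changed 9434 of 15152 genes (62.3%), 4733 upward and 4701 downward, and 768 rose and 1208 fell at least 2-fold. Counts are relative to the library total, so a change shared by all transcripts would not be visible.

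**Figure D3:**
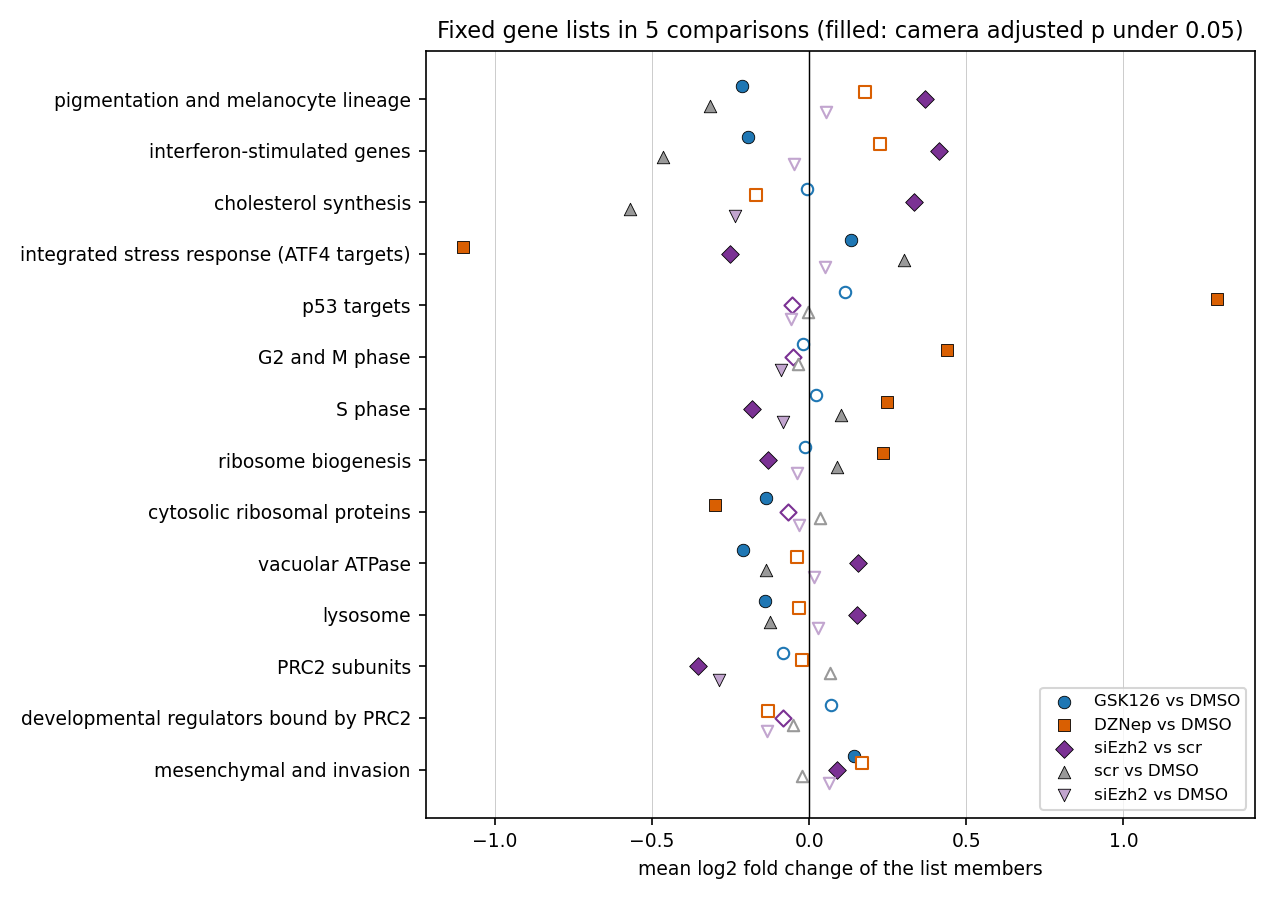
Mean log2 fold change of 14 gene lists on the vertical axis in 5 comparisons, with filled points where the camera adjusted p is under 0.05. Pigmentation genes lie at −0.215 with GSK126 and 0.369 with siEzh2 against scr, and at −0.315 in scr against DMSO.

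In the knockdown the largest increases against scr among the genes that the naming rule admits were in Vwf and Ccn4. Vwf, von Willebrand factor (chromosome 6, 125546774 to 125686679), rose 5.6-fold from 2.05 ± 0.354 to 11.6 ± 0.68 CPM (2.49 ± 0.13, adjusted p = 3.53e-11), with 5.99 ± 1.21 CPM in DMSO. Ccn4, a matricellular protein of Wnt signalling (chromosome 15, 66891320 to 66923201), rose 4.1-fold from 18.2 ± 0.641 to 74.5 ± 2.08 CPM (2.03 ± 0.05), with 33.6 ± 1.94 CPM in DMSO. The keratin Krt80 rose 3.52-fold, the cyclic GMP-dependent kinase Prkg2 and Spp1 (osteopontin) each rose 3.1-fold, and Ano3, which overlaps Muc15, rose 2.88-fold. Besides Ezh2, the largest decreases among the admitted genes were in Lrrc75b (7.42-fold, from 13.5 ± 1.23 to 1.81 ± 0.161 CPM), the matrix protein gene Sned1 (5.8-fold, −2.54 ± 0.13; chromosome 1, 93235841 to 93301065, overlapping Mterf4), the adhesion protein Cdsn (corneodesmosin, 5.67-fold), the ephrin receptor Epha5 (4.03-fold) and the receptor Notch1 (3.85-fold). The controls differed in several of these: Sned1 stood at 89.9 ± 5.28 CPM in scr, 15.4 ± 2.49 with siEzh2 and 16.3 ± 3.4 in DMSO, and Cdsn at 28.5 ± 1.78, 5.01 ± 0.32 and 5.11 ± 0.394. Against DMSO, siEzh2 gave −0.07 for Sned1 (adjusted p = 0.794), −0.02 for Cdsn (0.936) and −0.43 for Epha5 (0.128), whereas Vwf (0.96), Ccn4 (1.15), Krt80 (1.41), Lrrc75b (−1.08) and Notch1 (−0.63) kept their direction.

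Pigmentation genes rose in the knockdown, 23 of 33 with 1 lower (Slc7a11, a cystine transporter), or 23 and 2 when adjusted over the list alone (mean 0.369, adjusted p = 3.75e-18, and adjusted p = 0.000375 with an estimated correlation). Mlph, which links melanosomes to myosin (chromosome 1, 90915085 to 90951142), rose 2.2-fold from 186 ± 5.83 in scr to 409 ± 17.3 CPM, with 436 ± 21.2 CPM in DMSO. Oca2, a melanosome membrane protein, rose 2.05-fold and Bace2, a protease that cuts Pmel, 1.69-fold. In scr against DMSO 24 of the 33 fell and 2 rose, and siEzh2 against DMSO had 8 higher and 5 lower (mean 0.054, adjusted p = 0.126). Interferon-stimulated genes rose in 25 of 35, or 28 with 1 lower when adjusted over the list alone (mean 0.414, adjusted p = 7.14e-12, and adjusted p = 0.0194 with an estimated correlation). The guanylate-binding protein Gbp2 stood at 1.24 ± 0.09 and the RNA sensor Ifih1 at 0.59 ± 0.06. Of these 35, 27 fell in scr against DMSO, and siEzh2 against DMSO had 2 higher and 3 lower (mean −0.05, adjusted p = 0.347; Gbp2 0.18). Cholesterol synthesis genes rose in 21 of 25, or 22 when adjusted over the list alone (mean 0.332, adjusted p = 1.27e-11, and adjusted p = 0.144 with an estimated correlation). The enzymes Hsd17b7 and Msmo1 stood at 0.66 ± 0.07 and 0.49 ± 0.06. Their direction turned with the control: 23 of 25 were lower in scr than in DMSO, and with siEzh2 12 were lower than in DMSO (mean −0.237, adjusted p = 5.67e-10; Hsd17b7 −0.15, Msmo1 −0.24).

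Among 13 PRC2 subunits, Ezh2, Suz12, Epop, Phf19, Rbbp4 and Mtf2 fell, 6 in all, and Jarid2 rose, the same when adjusted over the list alone (mean −0.354, adjusted p = 4.04e-08, and adjusted p = 0.0018 with an estimated correlation). Ezh2 is the target of the siRNA, and without it the other 12 had a mean of −0.178 (adjusted p = 0.0418, and adjusted p = 0.161 with an estimated correlation), or −0.113 against DMSO (adjusted p = 0.131). Phf19 changed by −0.57 ± 0.07 against scr and 0.07 against DMSO, Jarid2 by 0.20 ± 0.05 and 0.07, and the list against DMSO had 4 lower (mean −0.288, adjusted p = 5.67e-10). S phase genes fell in 22 of 41, or 27 when adjusted over the list alone (mean −0.183, adjusted p = 2.39e-06, and adjusted p = 0.291 with an estimated correlation). The replication factors Cdc45 (−0.56 ± 0.05) and Mcm5 (−0.37 ± 0.05) were among them. In scr 12 of the 41 were higher and 1 lower than in DMSO, and siEzh2 had 8 lower and 1 higher than DMSO (mean −0.083, adjusted p = 0.00792; Mcm5 −0.06). ATF4 targets fell in 15 of 28, or 16 when adjusted over the list alone (mean −0.251, adjusted p = 3.34e-05, and adjusted p = 0.376 with an estimated correlation). The tRNA synthetase Wars stood at −0.60 ± 0.05 and the pseudokinase Trib3 at −0.83 ± 0.09. In scr 17 of the 28 were higher than in DMSO, and against DMSO the siEzh2 mean was 0.051 (adjusted p = 0.254; Trib3 0.23, Wars −0.11).

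Lysosome genes rose in 16 of 30 and fell in 2 (Sqstm1 and Glb1), or 17 and 2 when adjusted over the list alone (adjusted p = 0.000327, and adjusted p = 0.229 with an estimated correlation). The lipid hydrolase Asah1 stood at 0.42 ± 0.05, the hexosaminidase Hexa at 0.39 ± 0.05 and Glb1 (beta-galactosidase) at −0.19 ± 0.05, whose call was lost without scr replicate 3 (adjusted p = 0.0586). Against DMSO the lysosome mean was 0.027 (adjusted p = 0.399; Asah1 0.07, Hexa 0.00). The vacuolar ATPase had 6 of 16 higher, or 9 when adjusted over the list alone (adjusted p = 0.0102, and adjusted p = 0.421 with an estimated correlation). Its mean was 0.016 against DMSO (adjusted p = 0.874). Ribosome biogenesis had 16 of 40 lower, or 19 when adjusted over the list alone (adjusted p = 0.00214, and adjusted p = 0.378 with an estimated correlation). The small nucleolar ribonucleoprotein genes Nop56 and Dkc1 stood at −0.35 ± 0.06 and −0.32 ± 0.06, and the list had a mean of −0.04 against DMSO (adjusted p = 0.279). MHC class I presentation had 6 of 16 higher, also when adjusted over the list alone (adjusted p = 0.0232, and adjusted p = 0.378 with an estimated correlation). Against DMSO its mean was −0.13 (adjusted p = 0.13). Mesenchymal genes had 14 of 30 higher and 7 lower, or 15 and 7 when adjusted over the list alone (adjusted p = 0.0419, and adjusted p = 0.229 with an estimated correlation). That call was lost without scr replicate 1 (adjusted p = 0.0723) or 3 (0.0503), with no count filter (0.0631) and against DMSO (0.0736). The fibroblast markers Col1a1, Postn and Pdgfra rose, 3 of 6, or 3 with 1 lower when adjusted over the list alone (mean 0.382, adjusted p = 0.045, and adjusted p = 0.185 with an estimated correlation). The fibroblast list kept its call against DMSO (mean 0.315, adjusted p = 0.00562), where Postn stood at 1.02 (adjusted p = 3.94e-07) and Col1a1 at 0.29 (0.322), but Pdgfra was lower (−0.69, adjusted p = 0.000398). It lost it without scr replicate 3 (adjusted p = 0.0675), siEzh2 replicate 1 (0.0513) or siEzh2 replicate 2 (0.0666) and with no count filter (0.162).

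The remaining lists were not called in the knockdown against scr. The methionine cycle and polyamines had 1 higher (Ahcyl2) and 6 lower of 20, or 2 and 7 when adjusted over the list alone (mean −0.144, adjusted p = 0.0508). That list passed with no count filter (0.00693), by library totals (0.0435), with the replicate number as a block (0.0365) and without scr replicate 3 (0.0484) or siEzh2 replicate 1 (0.0201). In the following lists the numbers of higher and lower members were the same over all genes and when adjusted over the list alone. The unfolded protein response had 4 (Xbp1, Dnajc3, Edem1 and Calr) and 1 (Herpud1) of 21 (adjusted p = 0.139), and passed with no count filter (0.0348), without siEzh2 replicate 3 (0.0257) and, in the other direction, against DMSO (mean −0.152, 0.000994). G2 and M phase had 2 (Gas2l3 and Ckap2l) and 11 of 51 (adjusted p = 0.161), and passed with no count filter (0.0125) and against DMSO (0.00219). Clathrin genes had Ap3b1, Ap2a2, Ap1g1 and Ap1s2 higher, 4 of 20 (adjusted p = 0.185, and 0.0436 with no count filter). Neural genes had 4 and 2 of 10 with a median of −0.081 and a mean of 0.143 (adjusted p = 0.363). Cytosolic ribosomal proteins had 2 lower of 40, Rpl10a and Rps19 (adjusted p = 0.364), and p53 targets 2 (Sesn1 and Tnfrsf10b) and 7 of 27 (0.554). Developmental regulators bound by PRC2 had 4 and 4 of 36 (adjusted p = 0.669). Imprinted genes had Peg13, Impact, Sgce and Peg10 higher and Mest, Cdkn1c and Phlda2 lower of 10, with a median of 0.032 and a mean of −0.281 (adjusted p = 0.929). By edgeR, 0 of 4 germline, 0 of 13 mitochondrially encoded and 0 of 2 blood and endothelial genes were called, over all genes or adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 (adjusted p = 0.669, 0.887 and 0.977). Members named here outside the naming rule were chosen after their values were seen.

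The knockdown changed 3953 genes against scr (26.1%), 2000 upward and 1953 downward, with 150 higher and 182 lower at least 2-fold. The share of calls that were higher was 50.6%, or 42.2% when libraries were scaled by their totals alone. Against DMSO it changed 2148, a control added after seeing the data. Of the 3953 genes, 987 (25%) were called in the same direction against both controls, 483 higher and 504 lower, 125 (3.16%) were called in opposite directions and 2841 (71.9%) against scr alone. Of the same genes, 2189 (55.4%) had been called the opposite way in scr against DMSO.

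**Figure D4:**
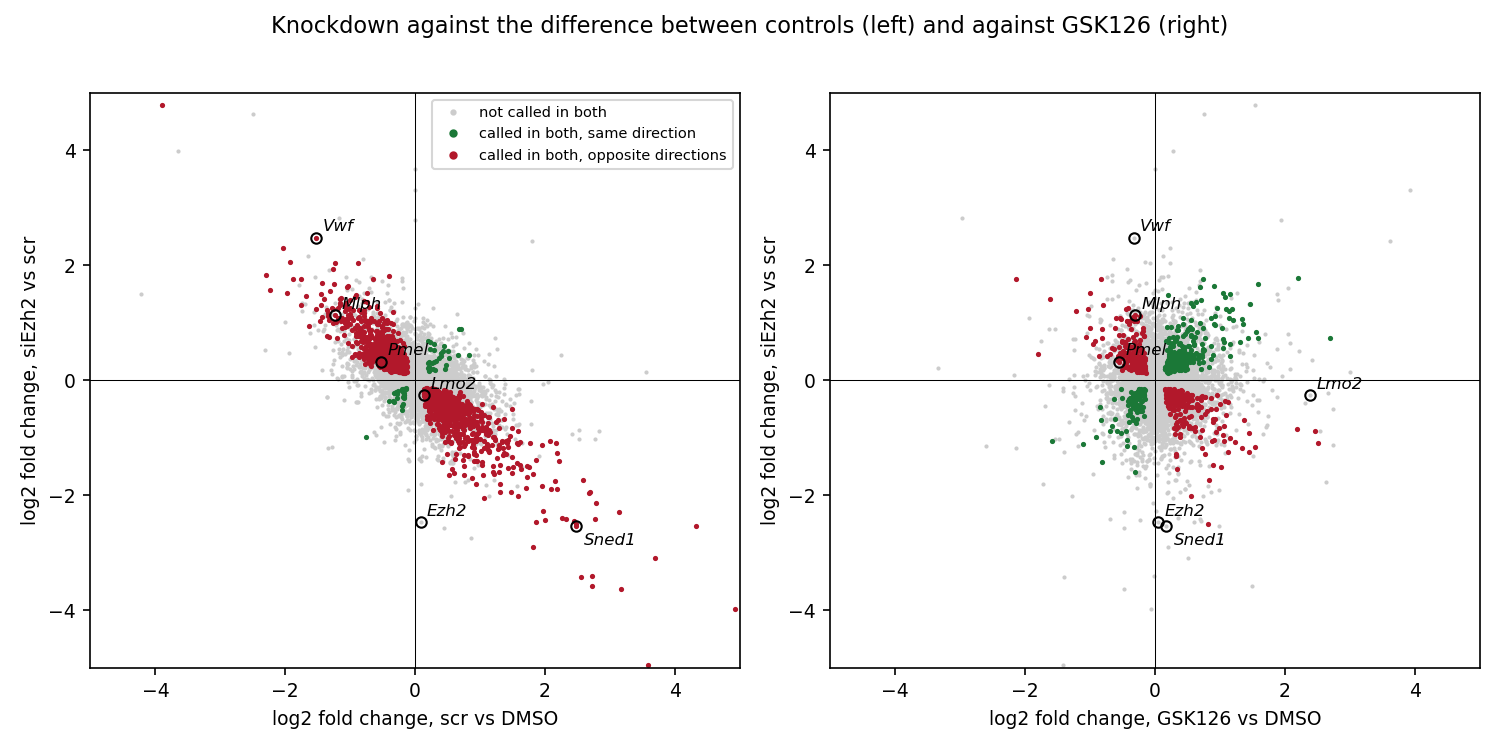
Log2 fold changes of every tested gene, siEzh2 against scr on scr against DMSO (left) and siEzh2 against scr on GSK126 against DMSO (right), where fitted values of genes at 0 counts depend on the prior count. Points on the left slope downward (r = −0.677, where unchanged groups sharing the scr libraries gave −0.49), and those on the right show little relation (r = 0.023).

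The scrambled siRNA libraries differed from the DMSO libraries in 3920 genes (25.9%), 1854 higher and 2066 lower. The share of calls that were higher was 47.3%, or 58.5% by library totals. With the replicate number within each arm as a block the count was 1881. These 2 groups lie in different arms, so that fit compares their levels at replicate 1 and does not measure the effect of blocking. The glutamate receptor subunit Grik3 was 6.02-fold higher in scr (2.59 ± 0.17, adjusted p = 1.8e-09), Cdsn 5.58-fold and Sned1 5.55-fold, and the growth factor receptor Pdgfra (which overlaps predicted genes) was 3.12-fold lower, Vwf 2.87-fold and the mitochondrial carrier Slc25a34 2.56-fold. Cholesterol synthesis fell in 23 of 25, or 24 when adjusted over the list alone (mean −0.569, adjusted p = 3.82e-35, and adjusted p = 0.00618 with an estimated correlation). Interferon-stimulated genes fell in 27 of 35, or 28 when adjusted over the list alone (mean −0.465, adjusted p = 3.51e-17, and adjusted p = 0.00396 with an estimated correlation). Pigmentation genes fell in 24 of 33 with 2 higher, or 26 and 2 when adjusted over the list alone (mean −0.315, adjusted p = 7.05e-15, and adjusted p = 0.000389 with an estimated correlation). ATF4 targets rose in 17 of 28, or 19 when adjusted over the list alone (adjusted p = 1.59e-08, and adjusted p = 0.22 with an estimated correlation). The unfolded protein response fell in 12 of 21 with 1 higher, or 14 and 1 when adjusted over the list alone (adjusted p = 6.57e-06, and adjusted p = 0.22 with an estimated correlation). MHC class I presentation fell in 11 of 16, also when adjusted over the list alone (adjusted p = 7.05e-05, and adjusted p = 0.18 with an estimated correlation). Lysosome genes fell in 11 of 30, or 14 when adjusted over the list alone (adjusted p = 0.00203, and adjusted p = 0.35 with an estimated correlation), and the vacuolar ATPase in 6 of 16, or 9 when adjusted over the list alone (adjusted p = 0.00849, and adjusted p = 0.441 with an estimated correlation). S phase genes rose in 12 of 41 with 1 lower, or 13 and 1 when adjusted over the list alone (adjusted p = 0.00749, and adjusted p = 0.563 with an estimated correlation). Ribosome biogenesis rose in 9 of 40, also when adjusted over the list alone (adjusted p = 0.022, and adjusted p = 0.563 with an estimated correlation). Transfection, vehicle and handling are confounded in this comparison.

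Whether the Ezh2 knockdown, which left 39.6 of 219 CPM of its transcript, and GSK126 acted alike was tested as the difference of effects, each against its own control. Vwf (2.81 ± 0.18), Sgk2 (2.26 ± 0.17) and Ccn4 (2.11 ± 0.07) had the largest positive differences of siEzh2 minus GSK126, and Sema3c (−3.35 ± 0.14), Cdsn (−3.32 ± 0.18) and Lrrc75b (−3.10 ± 0.16) the largest negative ones, among the genes that the naming rule admits. These differences, with DMSO as the control of siEzh2, were 1.29, 1.74 and 1.22, and −2.23, −0.85 and −1.29. Pigmentation differed in 26 of 33 upward and 2 downward, also when adjusted over the list alone (mean 0.584, adjusted p = 2.27e-29, and adjusted p = 1.49e-05 with an estimated correlation). Interferon-stimulated genes had 25 of 35 higher and 1 lower, or 29 and 1 when adjusted over the list alone (mean 0.61, adjusted p = 2.68e-14, and adjusted p = 0.00852 with an estimated correlation). The vacuolar ATPase had 13 of 16 higher, or 14 when adjusted over the list alone (mean 0.367, adjusted p = 7.11e-08, and adjusted p = 0.0801 with an estimated correlation). PRC2 subunits had 3 of 13 lower, or 4 lower and 1 higher when adjusted over the list alone (adjusted p = 0.000498, and adjusted p = 0.0206 with an estimated correlation), but without Ezh2, the target of the siRNA, that list was not called (mean −0.082, adjusted p = 0.528). In all 3132 genes (20.7%) differed, 1536 higher and 1596 lower. The share of higher genes was 49%, or 39.2% with library totals alone. The scr control enters this contrast. With DMSO in its place, DMSO cancels and siEzh2 is compared directly with GSK126, across arms in which transfection and handling are confounded. In that comparison 3084 genes differed, of which 1605 were among the 3132. The mean differences were 0.269 for pigmentation (adjusted p = 8.8e-14, and adjusted p = 0.000502 with an estimated correlation), 0.228 for the vacuolar ATPase (adjusted p = 3.46e-06, and adjusted p = 0.17 with an estimated correlation) and 0.145 for interferon-stimulated genes (adjusted p = 0.109).

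DZNep and the knockdown differed in 7748 genes (51.1%), 3835 higher and 3913 lower in DZNep minus siEzh2. Crabp2, a retinoic acid binding protein (4.82 ± 0.31), and the DNA polymerase gene Poln (4.68 ± 0.21; it overlaps Haus3) had large positive differences, and Akr1b7 (−6.36 ± 0.41), Apobr (−5.08 ± 0.33) and Spdya, a cell cycle activator (−4.17 ± 0.31), the largest negative ones among the admitted genes. With DMSO as the control of siEzh2 these were 4.26 and 3.35, and −7.86, −5.34 and −3.96. DMSO then cancels, so that setting compares DZNep directly with siEzh2, across the arms. Prl2c5 was also called, but with 3 counts in all scr libraries and 2 in all siEzh2 libraries no fold is given, and its call was lost without scr replicate 1 (adjusted p = 0.917). p53 targets were higher in 23 of 27 and lower in 3, also when adjusted over the list alone (mean 1.353, adjusted p = 4.35e-22, and adjusted p = 0.000287 with an estimated correlation). ATF4 targets were lower in 23 of 28 and higher in 2, also when adjusted over the list alone (mean −0.85, adjusted p = 8.86e-14, and adjusted p = 0.131 with an estimated correlation). S phase genes were higher in 32 of 41 and lower in 2, or 33 and 2 when adjusted over the list alone (mean 0.432, adjusted p = 2.09e-08, and adjusted p = 0.172 with an estimated correlation). With DMSO as the control of siEzh2 the mean differences were 1.356 for p53 targets (adjusted p = 2.73e-23, and adjusted p = 0.000364 with an estimated correlation), −1.153 for ATF4 targets (adjusted p = 5.09e-23, and adjusted p = 0.0471 with an estimated correlation) and 0.332 for S phase genes (adjusted p = 5.78e-05, and adjusted p = 0.405 with an estimated correlation).

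The compounds were compared directly at 2 µM. Prl2c5 was 184-fold higher with DZNep than with GSK126, where it had 5 counts over 3 libraries, Atp2a1 was 35.9-fold higher and Cyp4a10 32.1-fold, while Akr1b7 was 293-fold lower, Apobr 37.9-fold lower and Lmo2 21.3-fold lower (−4.41 ± 0.19, adjusted p = 1.04e-13). ATF4 targets were lower in 25 of 28 and higher in 2, also when adjusted over the list alone (mean −1.235, adjusted p = 9.41e-23, and adjusted p = 0.0272 with an estimated correlation). p53 targets were higher in 23 of 27 and lower in 2, also when adjusted over the list alone (mean 1.185, adjusted p = 4.07e-18, and adjusted p = 0.000779 with an estimated correlation). Pigmentation was higher with DZNep in 21 of 33 and lower in 7, also when adjusted over the list alone (mean 0.391, adjusted p = 2.78e-05, and adjusted p = 0.0159 with an estimated correlation). In all 9792 genes (64.6%) differed, 4985 higher and 4807 lower with DZNep.

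Genes that moved in more than 1 treatment were counted next. GSK126 and siEzh2 against scr shared 262 higher and 106 lower genes, where independent lists would share 143 and 108, and 443 genes went in opposite directions (250 for independent lists). Across genes, which are not independent replicates, their fold changes had r = 0.023 (jackknife SE 0.039, rho = 0.017) and a covariance of 0.00275 beside −0.000209 simulated. The shared lower genes numbered 47 without GSK126 replicate 1, 63 without replicate 2, 62 without replicate 3, 54 without DMSO replicate 3 and 186 without DMSO replicate 1, and 213 with no count filter. With DMSO as the control of both, r was 0.323 beside 0.455 simulated for unchanged groups, and 241 higher and 178 lower genes were shared (70 and 65 for independent lists) and 128 were opposite (138), and the covariance was 0.0307 beside 0.0183 simulated. DZNep and siEzh2 against scr shared 874 higher and 838 lower genes (625 and 606 for independent lists) with 1123 opposite (1231), and r was 0.229 (jackknife SE 0.033, rho = 0.13) beside a simulated 0.001 (covariance 0.072 beside 0.0000193). With no count filter r was 0.055 for this pair. Against DMSO these were 412 and 455 genes, with 696 opposite (669 for independent lists). GSK126 and DZNep, which share the DMSO libraries, had 351 higher and 254 lower genes in common (339 and 260 for independent lists) and 764 opposite (598). Their r was 0.033 (jackknife SE 0.073, rho = −0.018) beside 0.466 simulated for unchanged groups, and the covariance 0.0086 beside 0.0188. The lower genes in common numbered 114 without GSK126 replicate 1, 125 without replicate 2, 147 without replicate 3 and 154 without DMSO replicate 3, and with no count filter they numbered 413 and r was 0.307. The simulations shared 0 called genes in these pairs by edgeR, and since 3 controls cannot be split into groups of at least 2, part of any excess between comparisons with the same controls may come from them. In all 3 treatments 124 genes were higher and 43 lower, or 69 and 21 when siEzh2 had to be called against both controls. The 133 genes that rose at least 2-fold with GSK126 had a median log2 fold change of 0.03 in siEzh2 against scr (24 higher, 19 lower). The 19 that fell at least 2-fold had a median of 0.69 there. Against DMSO, whose libraries were also used to select these genes, the siEzh2 medians were 0.24 and 0.01.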

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

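The tests of chance from shared scr libraries, of a shift shared by scr and siEzh2, of the share of genes with the word ACTTCGA, of scr as the control for pigmentation and of scaling between the p53 and ATF4 lists were chosen after the result was seen, as were the comparisons with DMSO as the control of siEzh2. The results below stand out because effects measured against their own controls differed between treatments.

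Changes in the knockdown ran opposite to those of its control: of 3953 genes called in siEzh2 against scr, 2189 had been called the other way in scr against DMSO. Independent chance values of the single scr libraries did not account for this. The covariance of the 2 fold changes was −0.0974, and the simulated ones, drawn at the spread within groups, lay between −0.022 and −0.018. Nor did 1 scr library account for it, as at least 3025 genes were called in scr against DMSO with any 1 scr library left out. A deviation common to all scr libraries was not simulated and would remain with 1 left out, so these tests cannot exclude it. A shift common to transfected cells would carry over into siEzh2, but over the genes called in scr against DMSO the slope of siEzh2 against DMSO was 0.273 (jackknife SE 0.047), far below 1. A candidate explanation is an effect of the scrambled siRNA that siEzh2 lacked. Of 15954 words of 7 bases in 3′ UTRs, ACTTCGA alone passed a Bonferroni threshold of 0.05 for lower values in scr against the mean of DMSO and siEzh2 (mean shift −0.144, 224 of 12300 genes). The largest shift past that threshold with GSK126 was 0.043. Of genes with the word, 25.4% were called lower in scr and higher in siEzh2, against 9% of the others. The word was picked from fold changes of the same libraries, so these shares restate that choice and add no support. Yet the word was in only 4.98% of the genes that were lower in scr and higher in siEzh2 (1.82% of all genes). Direct matches of this word in annotated 3′ UTRs could therefore be a small part at most. Other words and sites outside 3′ UTRs were not counted, so the share of all direct matches is not known. Indirect effects of scr, differences in handling and a biological effect of Ezh2 knockdown stay open, and no siRNA sequence was used here.

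Pigmentation genes fell with GSK126 (mean −0.215) and rose with siEzh2 against scr (0.369), with a tested difference of 0.584. With DMSO as the control of siEzh2 it was 0.269, where DMSO cancels and siEzh2 is compared directly with GSK126 across the arms. The rise depends on the control: against DMSO the siEzh2 mean was 0.054, so the low level of these genes in scr may account for most of it. The fall with GSK126 kept its size without GSK126 replicate 1 (−0.209), whose library number is apart, and after removing trends with GC content and transcript length (−0.252, from −0.215 ± 0.033). Whether part of that fall comes from the DMSO libraries was not tested, but pigmentation genes were also lower in scr than in DMSO. GSK126 and scr, each against DMSO, shared 310 higher and 328 lower genes (133 and 114 for independent lists), with 229 opposite (250). Their covariance was 0.0279, above the 0.0162 to 0.021 simulated for unchanged groups sharing DMSO. A biological difference between GSK126 and Ezh2 knockdown remains open as a hypothesis for the part that the controls leave.

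With DZNep, p53 targets rose (mean 1.298 ± 0.229) and ATF4 targets fell (−1.101 ± 0.203, SE over genes). Removing GC content and length trends left 1.337 and −1.089, which argues against those trends as the cause. A wrong scaling of the libraries moves every gene alike, whereas the gap between the lists was 2.399 (SE 0.306). A response of these cells to DZNep stays open as a hypothesis, and dose and time were not tested here.

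Further differences between treatments are given as values. In siEzh2 minus GSK126, interferon-stimulated genes had a mean difference of 0.61 and vacuolar ATPase genes of 0.367 (adjusted p = 0.0801 with an estimated correlation). With DMSO as the control of siEzh2, which leaves siEzh2 directly against GSK126, these were 0.145 (adjusted p = 0.109) and 0.228. In DZNep minus siEzh2, the mean difference was −0.85 for ATF4 targets (adjusted p = 0.131 with an estimated correlation), 1.353 for p53 targets and 0.432 for S phase genes (adjusted p = 0.172 with an estimated correlation). With DMSO as the control, which leaves DZNep directly against siEzh2, these were −1.153 (adjusted p = 0.0471 with an estimated correlation), 1.356 and 0.332. Genes called in opposite directions numbered 443 for GSK126 and siEzh2 (250 for independent lists) and 764 for GSK126 and DZNep (598). For DZNep and siEzh2 they numbered 1123, below the 1231 for independent lists. The difference itself was called for all of these genes. Opposite calls make that nearly certain, so it adds no support. With DMSO as the control of siEzh2, opposite genes numbered 128 (138 for independent lists) with GSK126 and 696 (669) with DZNep. These pairs share the DMSO libraries, which alone push fold changes the same way (r of 0.455 simulated for unchanged groups). These counts therefore do not show whether the excess of opposite genes between GSK126 and siEzh2 comes from scr. Genes called in the same direction with GSK126 and with siEzh2 against scr also exceeded independent lists (368 beside 251). The excess for that pair was thus not confined to opposite genes. For GSK126 and DZNep, genes called in the same direction numbered 605 (599 for independent lists).

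For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. In each, 1 of the 10 splits, the real one, gave as many genes, and the highest other split gave 0 by edgeR. The real counts, and the highest number of genes at an unadjusted p under 0.05 in any other split, were 1923 and 1337 for GSK126, 9434 and 1936 for DZNep, 3953 and 857 for siEzh2 against scr, 9792 and 541 for DZNep against GSK126, and 3920 and 1529 for scr against DMSO. For siEzh2 minus GSK126, 2 of 100 splits gave at least the real 3132 genes, the highest other giving 4003. For DZNep minus siEzh2, 2 of 100 gave at least the real 7748, the highest other giving 8727. In both, that other split exchanges all scr and DMSO libraries and so follows the difference between the controls. Most other splits mix libraries of groups that differ, which widens the spread within a group and lowers the count. These shares, though under 0.05, therefore cannot exclude chance.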

How the results depend on the processing

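DMSO as the control of siEzh2, scaling by library totals and the PRC2 list without Ezh2 were chosen after the result was seen. Of the alternatives run, 1668 comparisons of named genes with an alternative kept the call and, where called, the direction. Another 28 lost the call, 6 turned direction with a call in at least 1 setting, and 1 gained a call. For lists these were 828, 41, 5 and 17, and 22 of the 41 losses came from the estimated correlation. A turn of direction between 2 uncalled results counts among those kept. The direction of a list is that of its camera test. The neural list with GSK126 and no count filter, whose mean turned to −0.016, therefore counts as a loss. Among counts of genes 92 stayed within 1.5 times and 14 did not, among overlaps 86 and 14, and among correlations 43 stayed within their jackknife SE and 4 did not. Of those 43, 33 left out 1 library. That SE was computed from these same values, so they could hardly exceed it. RLE factors and DESeq2 moved no such count past 1.5 times. The causes of these moves were not tested unless given below.

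With only the compared groups in the fit, which leaves fewer libraries to estimate the spread, GSK126 changed 1131 genes, and with 1 library left out between 1201 and 2498. Only the compared groups gave 4289 genes for siEzh2 against scr and 10029 for DZNep against GSK126, above the main 3953 and 9792. In the other comparisons that setting gave fewer genes than the main fit. An absolute log2 fold change of at least 1 left 152 genes for GSK126, 1976 for DZNep, 332 for siEzh2, 477 for siEzh2 minus GSK126, 1837 for DZNep minus siEzh2, 2184 for DZNep against GSK126 and 316 for scr against DMSO. With no count filter r was 0.307 for GSK126 and DZNep and 0.055 for DZNep and siEzh2, and the shared lower genes were 413 for GSK126 and DZNep and 213 for GSK126 and siEzh2. Leaving out 1 library gave 114 to 356 and 47 to 186 of these.

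DMSO as the control of siEzh2 gave 2148 genes, r of 0.323 with GSK126 and 0.194 with DZNep (each beside 0.455 simulated for unchanged groups sharing DMSO), 178 shared lower genes with GSK126, and 412 higher and 455 lower with DZNep. It turned the means of interferon-stimulated genes (−0.05), MHC class I presentation (−0.13), cholesterol synthesis (−0.237), ATF4 targets (0.051) and the unfolded protein response (−0.152). It also turned Mlph (−0.093), Hsd17b7 (−0.145), Msmo1 (−0.244), Phf19 (0.074) and Trib3 (0.228), and left Hexa at 0.

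Replicate numbers did not pair the libraries: of 12 pairs with the same number 0 had a correlation of deviations over 0.1 (−0.176 to 0.091), and the own number was best in 4 of 12. With the replicate number as a block, 1879 genes were called for GSK126, 9385 for DZNep, 3849 for siEzh2, 3017 and 7629 for the differences between effects and 9742 for DZNep against GSK126. For scr against DMSO 1881 were called, where 3920 were called without it. That comparison crosses the arms, so the blocked fit compares levels at replicate 1 and its lower count does not measure the effect of blocking. The block added the calls of pigmentation with DZNep (adjusted p = 0.0487) and methionine cycle genes with siEzh2 (adjusted p = 0.0365) and changed no other call of a list in the 3 main comparisons or of a named gene. Under the block r was 0.032 for GSK126 and DZNep, 0.021 for GSK126 and siEzh2 and 0.23 for DZNep and siEzh2, with 333, 259 and 838 shared higher and 248, 122 and 828 shared lower genes.

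Depth limits the least expressed genes, where 1 count is worth up to 0.03 CPM. Of the developmental regulators bound by PRC2, 46 of 82 did not pass the count filter, and whether depth or a lack of expression was the reason was not tested.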

Other observations

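All tests of gene families and of the protocadherin cluster were chosen after the result was seen, and the genes named were chosen after their values were seen. The test of the Ezh2 siRNA was set before its own result was seen, but its words came from the scan of 3′ UTR words in these data. It was set for the longest Ezh2 transcript alone and was run on all annotated ones. Within imprinted genes, Cdkn1c, which encodes the cyclin-dependent kinase inhibitor p57, fell with DZNep (log2 −3.02 ± 0.51, adjusted p = 3.04e-05) and with siEzh2 against scr (−2.14 ± 0.22, adjusted p = 3.85e-07), and stood at −0.03 with GSK126. It was higher in scr than in DMSO (2.78 ± 0.23), and siEzh2 against DMSO gave 0.64 (adjusted p = 0.147). Ngfr, the low-affinity nerve growth factor receptor of neural crest cells, rose with GSK126 (1.44 ± 0.19, adjusted p = 2.88e-05) and fell with siEzh2 against scr (−1.24 ± 0.21) and with DZNep (−0.72 ± 0.24, adjusted p = 0.0144). It was higher in scr than in DMSO (0.90 ± 0.20), and siEzh2 against DMSO gave −0.34 (adjusted p = 0.36), so the fall against scr may come from that control. The receptor kinase Axl fell with DZNep (−0.93 ± 0.08) and with siEzh2 against scr (−1.30 ± 0.07) and against DMSO (−0.48 ± 0.07), and was at 0.14 with GSK126 (adjusted p = 0.206). Ahcy, which encodes the enzyme that DZNep inhibits, rose by 0.26 ± 0.10 with DZNep (adjusted p = 0.0379), and Mat2a, which makes S-adenosylmethionine, fell by 0.83 ± 0.05.

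Protocadherin beta genes, adhesion genes in a cluster on chromosome 18 (37294812 to 37524479, GRCm38), had a median log2 fold change of 0.44 with GSK126 over 17 genes, of which 16 were positive and 6 called. With DZNep the median was −1.04 (10 called lower), with siEzh2 −0.46 against scr (2 called lower) and −0.27 against DMSO. Among 154 gene families in 5 comparisons, 770 tests, 12 passed with camera, this family with GSK126 among them (adjusted p = 0.00585, and adjusted p = 0.982 with an estimated correlation). The collagen family was higher in scr against DMSO, 9 of 23 with 1 lower (adjusted p = 0.00018, and adjusted p = 0.632 with an estimated correlation). The nearby gamma protocadherins had medians of the same sign over 5 genes, 0.313 with GSK126, −1.177 with DZNep and −0.602 with siEzh2 against scr, and the 1 alpha gene, Pcdha11, was at 1.045, −0.534 and 0.642 (called in none). All 37 other genes within 1 Mb of the beta cluster, the alpha and gamma genes included, had medians of 0.039 with GSK126, −0.008 with siEzh2 and 0.263 with DZNep, which argues against a change of the whole neighbourhood. Along the cluster the GSK126 change fell with position (rho = −0.875 across 17 genes, permutation p = 2e-05, adjusted 6e-05), from Pcdhb2 (1.59 ± 0.38), Pcdhb3 (2.74 ± 0.53) and Pcdhb5 (1.02 ± 0.17) at the start to 0.12 for Pcdhb16, the 11th, with 0.44 for Pcdhb20, 0.38 for Pcdhb21 and 0.11 for Pcdhb22 at the end. DZNep (rho = 0.186, permutation p = 0.471, adjusted 0.658) and siEzh2 (rho = 0.115, permutation p = 0.658) did not pass. The genes are closely related and Pcdhb3 rose only from 0.044 to 0.33 CPM, so shared reads could contribute.

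Genes with the 3′ UTR word GCTAGAA were lower with siEzh2 against the mean of DMSO and scr (mean shift −0.053 over 1163 genes, past a Bonferroni threshold of 0.05). With GSK126, where no siRNA was given, 6 words passed that threshold for lower and 1 for higher values, with shifts up to 0.043. The test takes genes as independent, so a shift of this size need not come from an siRNA. Seed matches of the Ezh2 siRNA were tested as an explanation. The joined word AGCTAGAA and the word GCTAGAA occurred 0 times on either strand of the 15 annotated Ezh2 transcripts. No other part of the joined word was searched, and a pool of siRNAs would leave the question open. The test therefore cannot exclude seed matches of the Ezh2 siRNA.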
